A study of Mus musculus with 16 samples.

How the data were processed

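MicroRNAs (miRNAs, short RNAs that repress messenger RNAs) were measured in total RNA of RAW264.7, a mouse macrophage-like cell line. Per the labels, cells were grown for 48 h in medium alone or with interleukin-4 and interleukin-13 (IL-4 and IL-13, the Th2 cytokines, 10 ng per ml), then left unstimulated or given interleukin-33 (IL-33, 20 ng per ml) for 4 h. The 4 groups are called Media, Th2, Media_IL33 and Th2_IL33, and each holds 4 arrays, 1 from each of 4 independent experiments. Replicate numbers 1 to 4 stand for those experiments, so the labels pair the arrays across groups by number.

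Each sample was hybridised to 1 single-colour (Cy3) Agilent mouse miRNA array. Per the file headers, the scans were read with Agilent Feature Extraction 10.7.3.1, and the deposited scanner files give the intensity of every spot after subtraction of background and spatial trend, with no normalization between arrays. The authors also deposited a table of probe intensities for the 16 arrays. Per the submitters' processing notes it was made with Partek 6.6 and RMA. Its 3105 probes have a median of 0.428 and a maximum of 114686 in each column, so the values are quantile normalized intensities on the linear scale, neither log transformed nor centred. It holds 23296 values below 0. Each column ranks the probes as the mean spot signal of its own array does (Spearman correlation 1 on all 16 arrays).

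The values used here were computed from the scanner files. Control spots and spots that the scanner software marked as outliers were left out, the spots of a probe were averaged, and the probes of a miRNA were summed on the linear scale. Of the 1247 mouse miRNAs on the array, 4 have 1 probe, 901 have 2, 69 have 3 and 273 have 4. Each array was divided by its 75th percentile over the 178 miRNAs detected on all arrays. The result is called relative signal, so that 1 is the signal at that percentile. An alternative scaling used the percentile over all 1247 miRNAs. Fewer miRNAs were detected per array than lie above it, so that scaling rests on signals near background. Values under 0.0353, the 1st percentile of the detected signals, were set to that floor (log2 of -4.82) before the log2 was taken. The tests cover 231 miRNAs that the scanner software called detected on all 4 arrays of at least 1 group.

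The number of arrays limits the precision. The median standard error of a log2 difference between groups was 0.18. No spot was saturated. A probe was counted as well above background where at least 1 of every 2 of its spots was so marked, and a miRNA as not above background on an array where none of its probes was. If a miRNA was above background on no array of the dimmer group, the fold is given as "at least". It is then taken against the lowest signal well above background on each array of that group, or the measured signal where that was higher. Where some arrays of the dimmer group were above background, a second fold set the others in the same way.

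Groups were compared with limma 3.58.1 in R 4.3.3 (files read with the package data.table, version 1.17.8). A linear model with 1 mean per group was fitted to all 16 arrays (12 residual degrees of freedom), with moderated variances. The 5 comparisons were Th2 with Media, Media_IL33 with Media, Th2_IL33 with Th2, Th2_IL33 with Media_IL33, and the interaction, which is the IL-33 difference in Th2-grown cells minus that in medium-grown cells. Adjusted p values are Benjamini-Hochberg values over the 231 miRNAs within a comparison, with a threshold of 0.05. Errors of log2 differences are standard errors (SE) from the model, and those of group means are standard deviations (SD, n = 4). Direction counts over 4 experiments compare arrays of the same replicate number.

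The miRNAs named in a comparison were, of those past the threshold, the 12 with the largest increase and the 12 with the largest decrease. Where fewer than 10 passed, the 10 with the smallest unadjusted p were named. In every comparison miR-155-5p, miR-146a-5p, miR-21a-5p, miR-223-3p and miR-378a-3p were added, with up to 4 members of each list described. Any other miRNA is named because it passed the threshold or shares a gene with one that did, and was chosen after its values were seen. The 14 miRNA lists were inflammatory (induced by Toll-like receptor or NF-kB signals), alternative activation, myeloid, miR-17-92 with its paralogs, let-7, miR-15 with miR-16, miR-23 with miR-27 and miR-24, miR-29, miR-30, miR-221 with miR-222, stress, other cells or serum, the Sfmbt2 cluster family and the Dlk1-Dio3 cluster. Lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The counts of list members past the threshold are given over all tested miRNAs and adjusted over the list alone. The model, threshold, lists, rule for names and alternatives were fixed before the data were examined. The exception is the refit without 3 arrays that stand apart, which was chosen after seeing the data.

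The arrays lie on 2 slides of 8 arrays each, scanned in 2 batches that coincide with the slides. Slide 1 holds 3 Media, 3 Th2, 2 Media_IL33 and 0 Th2_IL33 arrays, and slide 2 holds 1, 1, 2 and 4. Every comparison was refitted with slide as a block and, where a slide held both groups, within it. The arrays within a slide also set the calls, so the direction of called miRNAs there is not separate support. Pairing was checked on residuals from the group means. Same-numbered arrays of different groups had a median correlation across miRNAs of 0.112 (24 pairs) and different-numbered arrays -0.0482 (72 pairs). Residuals cancel within a group, so a positive value for the first tends to force a negative one for the second, which is no separate baseline. A block for replicate number was among the alternatives. The other alternatives changed the scaling, background correction, probe summary, detection filter, floor, test and array weights, and each array was left out in turn. The normexp background correction added a constant to every spot before probes were summed, so it draws log2 differences of dim miRNAs toward 0.

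In 20 runs of simulated data (231 miRNAs, 40 changed per run in Th2), the test of Th2 with Media recovered 51.4% of changes of 1.5-fold, 80.8% of 2-fold and 87.3% of 3-fold. Of its calls, 5.22% were false. The simulated noise was independent for each miRNA and array, without correlated miRNAs, arrays that stand apart, slides or pairing. These rates need not hold for the real arrays. Of the 52 calls over all comparisons, 48 had every probe of the miRNA moving the same way. The exceptions were miR-100-5p (1 of 2 probes) and miR-362-5p (3 of 4) in both comparisons of Th2 cytokines. Probes of miR-378a-3p, miR-378b and miR-378d target nearly the same sequence, as do those of miR-99a-5p and miR-100-5p, so these signals are not separate measurements. The reference gene table is of assembly GRCm38.p6 and the array design names another build, so no coordinates are given. That table served only for host and neighbouring genes, and 189 of the 231 tested miRNAs matched 1 gene. Targets of the miRNAs were not analysed here.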

Results

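MicroRNA levels were measured in 16 arrays of RAW264.7 macrophage-like cells, 4 in each of Media, Th2, Media_IL33 and Th2_IL33. The series asks how growth in Th2 cytokines, the cytokines of allergic inflammation, changes the response of macrophages to IL-33, an alarm cytokine released by damaged epithelium. Each array carried 49880 miRNA spots, of which 2040 to 3929 were marked as outliers. The scanner software detected 206 to 256 miRNAs per array, and the 75th percentile used for scaling lay between 427 and 654 intensity units. Across the 231 tested miRNAs, arrays of the same group correlated with a median r of 0.985 (range 0.811 to 0.997, 24 pairs), and arrays of different groups with a median of 0.962 (96 pairs). Media replicate 3 had the lowest median correlation with its own group (0.874), followed by Media 1 and Media 2 (0.920 each) and Th2_IL33 2 (0.945). The first principal component held 43.0% of the variance and the second 27.5%.

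Growth in Th2 cytokines without IL-33 (Th2 with Media) changed 22 of 231 miRNAs, 20 higher and 2 lower, each moving the same way in 4 of 4 experiments. The smallest adjusted p was that of miR-511-3p, made from an intron of the mannose receptor gene Mrc1, a marker of alternatively activated macrophages. Its relative signal was 0.234 ± 0.0133 (SD, n = 4) in Th2, while every Media array was at the floor of 0.0353, so it was at least 4.45-fold higher (log2 difference from the floor 2.73 ± 0.10 SE, adjusted p = 8.18e-12). All Media and Media_IL33 arrays hold the same floor value for it and add no spread to the shared variance. Its SE and p therefore partly reflect the floor. Of 6 tested miRNAs encoded in the chloride channel gene Clcn5, 4 passed with it. Among them miR-500-3p went from 0.121 ± 0.0320 to 0.457 ± 0.0353 (3.89-fold, adjusted p = 9.76e-07), miR-532-5p rose 3.80-fold, miR-362-3p 4.15-fold and miR-362-5p at least 2.58-fold. The myeloid miRNA miR-223-3p rose 2.18-fold, from 0.444 ± 0.116 to 0.980 ± 0.264 (adjusted p = 0.00495).

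Other increases with Th2 cytokines were of 2.77-fold for miR-146b-5p (log2 difference 1.47 ± 0.22) and 2.31-fold for miR-342-3p. miR-378a-3p, which lies in the gene of the metabolic coactivator PGC-1beta (Ppargc1b), rose 2.10-fold from 0.158 ± 0.0280 to 0.330 ± 0.0492, with log2 differences of 1.19 for miR-378d and 1.16 for miR-378b. miR-99a-5p rose 2.12-fold, and its sequence relative miR-100-5p had a log2 difference of 1.01. Smaller increases were those of miR-21a-5p, a bright miRNA (18.7 ± 4.07 with 11.1 ± 3.92, 1.74-fold, adjusted p = 0.0386), the p53-responsive miR-34a-5p (1.72-fold), let-7c-5p (1.57-fold), miR-125b-5p (log2 difference 0.75), miR-22-3p (0.68), miR-27b-3p (0.68) and miR-23b-3p (0.64). The miRNAs that fell were members of 1 cluster, miR-96-5p (0.117 ± 0.0431 to 0.0444 ± 0.0182, log2 difference -1.41 ± 0.31, adjusted p = 0.00573) and miR-182-5p (at least 1.52-fold lower, adjusted p = 0.00969). For miR-96-5p 3 of 4 Th2 arrays were not well above background, so its fold depends on the floor. With such arrays at the lowest signal well above background the fold was 1.95 for miR-96-5p, 3.39 for miR-362-3p, 3.74 for miR-532-5p and 2.33 for miR-146b-5p. The NF-kB-responsive miR-155-5p (0.030 ± 0.19, adjusted p = 0.966) and miR-146a-5p (0.31 ± 0.16, adjusted p = 0.255) did not pass. For miR-155-5p, well above background on 1 of 4 Media and 0 of 4 Th2 arrays, a change below background would not be seen.

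**Figure D1:**
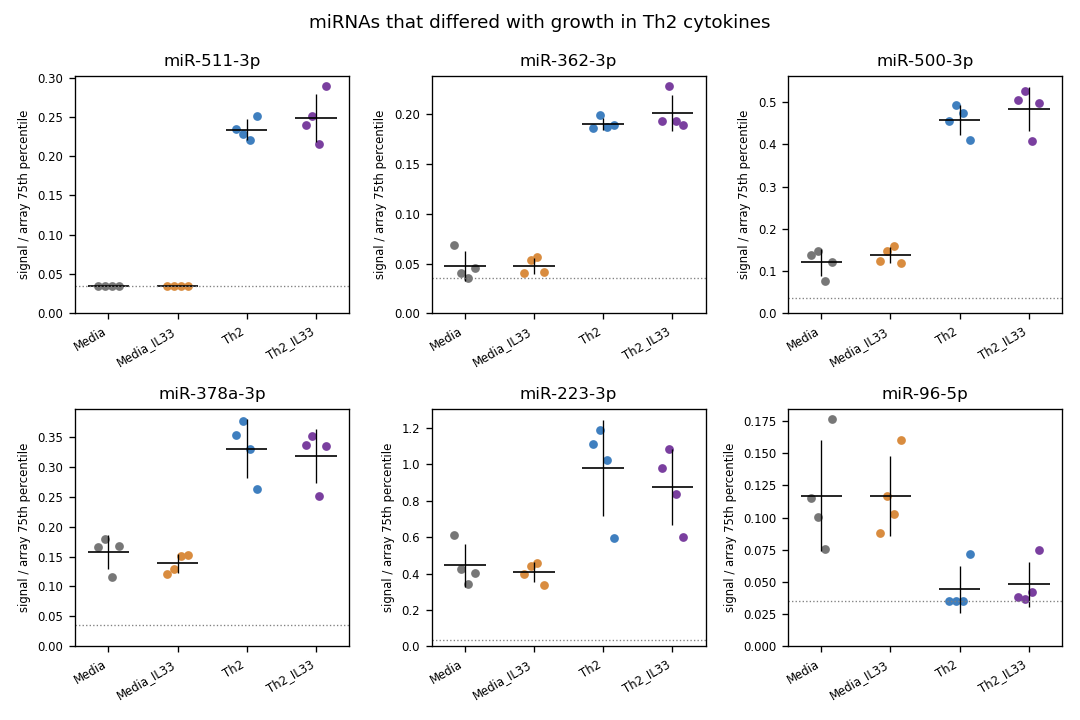
Relative signal (linear axis, 1 is the array's 75th percentile) of 6 miRNAs in the 4 groups, with 1 point per array, a black line at the mean, a bar of 1 SD (n = 4) and a dotted line at the floor. miR-511-3p is at the floor on all Media arrays, and its mean is 0.234 in Th2.

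Of the lists, alternative activation rose with Th2 cytokines (10 tested members, mean log2 difference 0.97, median 0.86, adjusted p = 0.000432, and 0.435 with an estimated correlation). It held 5 members past the threshold (miR-511-3p, miR-342-3p, miR-223-3p, miR-378a-3p and let-7c-5p), and 8 adjusted over the list alone. The 8 include miR-378a-5p (2.20 ± 0.93, limma adjusted p = 0.159, and 0.0458 over the list alone). It was 3.85 log2 units lower on the mean of Media 1 and 3 than on Media 2, so the list's mean rests in part on single arrays. Without Media 1, Media 3 and Th2_IL33 2 that mean was 0.81 (median 0.75, list adjusted p = 0.000268). The list's mean was 1.08 (median 1.01) within slide 1. Between the single arrays of slide 2, of which Media 1 stands apart, it was 0.62 (median 0.12), and with normexp background correction it was 0.42 (median 0.50). The miR-17-92 list, miRNAs of proliferating cells, fell by 0.21 on average (11 members, 0 past the limma threshold, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05, list adjusted p = 0.00372). Its adjusted p was 0.705 with an estimated correlation, and the means within the slides were -0.076 and -0.62. The largest differences in it were those of miR-92a-3p (-0.40) and miR-19a-3p (-0.37). The Sfmbt2 family is defined by miRNA name, and of its 32 tested members 20 lie in the rodent-specific intron cluster of Sfmbt2, 7 elsewhere and 5 match no single gene. It fell by 0.19 on average (32 members, median -0.13, 0 past the limma threshold, 0 adjusted over the list alone and 6 at an unadjusted p under 0.05, list adjusted p = 0.000519). Its adjusted p was 0.705 with an estimated correlation, and the means were -0.58 within slide 1 and 0.99 between the single arrays of slide 2. Without Media 1, Media 3 and Th2_IL33 2, arrays that stand apart, its adjusted p was 0.0754. With array weights 10 of its members passed the limma threshold as lower. With a block for replicate number miR-466f-5p (limma adjusted p = 0.0376) and miR-466j (0.0377) did.

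The near absence of decreases depends on single arrays and on the processing: without Media 3 30 miRNAs passed, 17 higher and 13 lower, and with quantile normalization 29, 18 higher and 11 lower. With slide as a block 20 of these 22 calls remained, without miR-21a-5p (adjusted p = 0.0503) and miR-27b-3p (0.0506). Within slide 1 (3 arrays of each group) 19 miRNAs passed and 15 of 15 named ones kept their direction (log2 -1.64 to 2.69). These 15 were called on the same arrays, most of them on slide 1, so that agreement was nearly built in. Between the single arrays of slide 2 14 of 15 kept it (-0.69 to 2.83) and miR-223-3p differed by -0.030. The calls that single arrays ended were miR-21a-5p without Media 2 or 3 or Th2 1, 2 or 4 (adjusted p 0.0528 to 0.0928), miR-23b-3p without any Th2 or Media array but Media 4 (0.0548 to 0.0954) and miR-27b-3p without Media 2 or 3 or any Th2 array (0.0662 to 0.131). Without the 3 arrays that stand apart, 21 miRNAs passed (16 higher, 5 lower), without miR-21a-5p (0.146), miR-22-3p (0.0530), miR-23b-3p (0.188) and miR-27b-3p (0.138). That refit added miR-183-5p (log2 difference -0.60, adjusted p = 0.00984), miR-466i-5p (-0.57, 0.0382) and miR-99b-5p (-0.68, 0.0423). With normexp background correction the log2 differences of miR-96-5p (-0.29) and miR-182-5p (-0.24) did not pass, and over the alternatives run for named miRNAs the adjusted p of miR-21a-5p was 0.00397 to 0.151.

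Stimulation of medium-grown cells with IL-33 (Media_IL33 with Media) raised 4 of 231 miRNAs and lowered 0 (14 had an unadjusted limma p under 0.05), each higher in 4 of 4 experiments. All 4 belong to the inflammatory list. miR-21a-3p, the partner strand of miR-21a-5p, rose 3.82-fold from 0.0562 ± 0.0207 to 0.206 ± 0.0327 (SD, n = 4 each, log2 difference 1.93 ± 0.24 SE, adjusted p = 0.000252). miR-146a-5p, an NF-kB-induced brake on Toll-like receptor and IL-1 receptor signalling, rose 2.11-fold from 0.231 ± 0.0336 to 0.484 ± 0.0568 (adjusted p = 0.000804). miR-155-5p, induced in activated macrophages, rose 2.25-fold from 0.0413 ± 0.0113 to 0.0913 ± 0.0112 (adjusted p = 0.00190), and miR-146b-5p 1.93-fold from 0.0495 to 0.0944 (adjusted p = 0.0319). On Media arrays miR-155-5p was well above background on 1 of 4, and miR-21a-3p and miR-146b-5p on 2 of 4. With the other arrays at the lowest signal well above background the folds were 1.59, 3.23 and 1.62.

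miR-21a-5p had a log2 difference of 0.59 ± 0.23 with IL-33 (adjusted p = 0.480), miR-222-5p of 0.65 ± 0.19 (0.179) and miR-125a-5p of 0.51 ± 0.18 (0.353), none past the threshold. With blocks for both slide and replicate number miR-222-5p passed (log2 difference 0.74, limma adjusted p = 0.0413). miR-376c-3p differed by 3.49 ± 1.20 (higher in 3 of 4 experiments), miR-378a-5p by 2.69 ± 0.93 and miR-3063-3p by 2.62 ± 0.92, each with an adjusted p of 0.353. The Th2-responsive miR-223-3p (-0.099) and miR-378a-3p (-0.17) did not pass (adjusted p of 1). The inflammatory list rose (9 tested members, mean 0.80, median 0.59, adjusted p = 4.34e-20), with 4 members past the threshold and 6 adjusted over the list alone. This held with an estimated correlation (adjusted p = 0.00422), the means within the slides were 0.94 and 0.57, and with normexp background correction the mean was 0.22 (median 0.12). No other list passed. The miR-221 with miR-222 list had an adjusted p of 0.115, and the Sfmbt2 family had a positive mean (0.076) and median (0.10) while its test pointed down (adjusted p = 0.652).

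With slide as a block 3 of the 4 calls remained, without miR-146b-5p (adjusted p = 0.0612). Within slide 1 (2 arrays with 3) the 4 log2 differences were 0.95 to 2.10 and 2 passed, and within slide 2 (2 with 1) they were 0.76 to 1.65. miR-146b-5p also did not pass without Media 2 (adjusted p = 0.0675) or 3 (0.122) or Media_IL33 1 (0.108), 2 (0.126) or 3 (0.138). Without the 3 arrays that stand apart, miR-155-5p (log2 difference 0.98, adjusted p = 0.0629) and miR-146b-5p (0.86, 0.108) did not pass. With normexp background correction miR-146a-5p passed alone, and the log2 differences were 0.24 for miR-21a-3p, 0.12 for miR-155-5p and 0.093 for miR-146b-5p. Over the alternatives run for named miRNAs the adjusted p was 0.00103 to 0.437 for miR-155-5p and 0.0245 to 0.600 for miR-146b-5p.

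In cells grown in Th2 cytokines IL-33 (Th2_IL33 with Th2) again raised 4 miRNAs and lowered 0 (6 at an unadjusted limma p under 0.05), each in 4 of 4 experiments. miR-155-5p rose at least 2.79-fold, from 0.0417 ± 0.00868 to 0.151 ± 0.0292 (SD, n = 4 each, log2 difference 1.86 ± 0.19 SE, adjusted p = 2.38e-05). miR-21a-3p rose 2.70-fold from 0.0825 to 0.217 (1.43 ± 0.24, adjusted p = 0.00366), and miR-146a-5p 1.87-fold from 0.287 ± 0.0512 to 0.533 ± 0.0798 (0.90 ± 0.16, adjusted p = 0.00366). The fourth was miR-222-5p, partner strand of the miR-222-3p that represses the cell cycle inhibitor p27, at 1.77-fold (0.112 to 0.196, adjusted p = 0.0338). miR-146b-5p (0.42), miR-21a-5p (0.40), miR-223-3p (-0.15) and miR-378a-3p (-0.053) did not pass (adjusted p of 1 each), nor did miR-125a-5p (0.50, 0.658), miR-99b-5p (0.55), let-7e-5p (0.35), miR-1198-5p (0.43) and miR-652-5p (0.30).

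**Figure D2:**
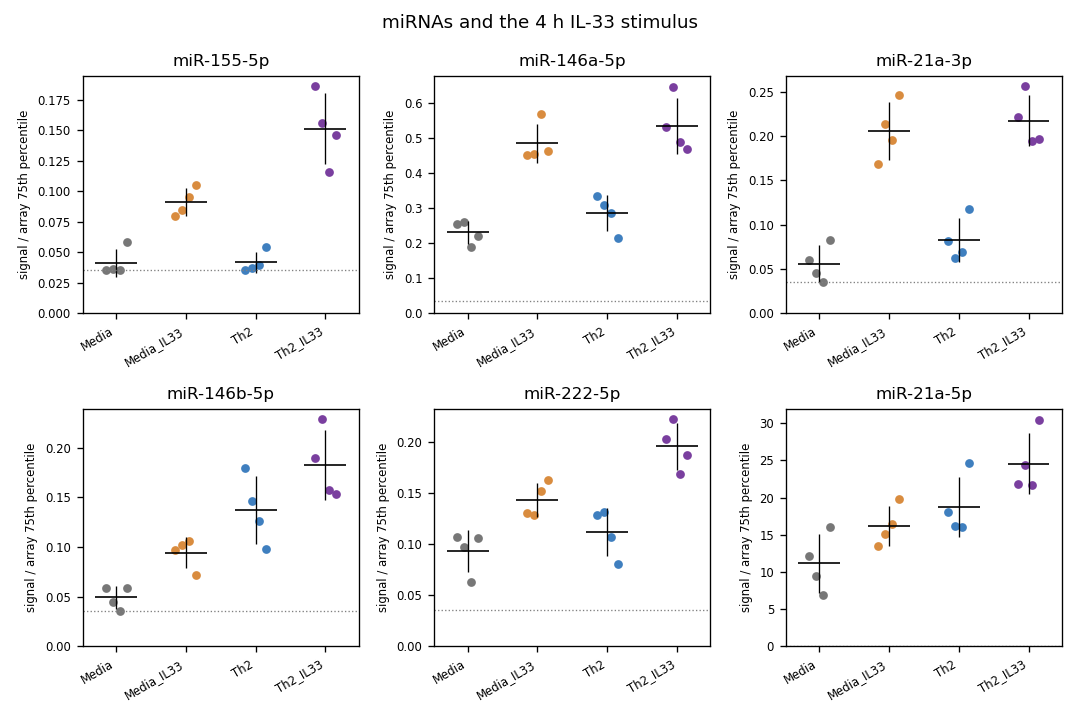
Relative signal (linear axis) of 6 miRNAs in the 4 groups, with 1 point per array, a black line at the mean, a bar of 1 SD (n = 4) and a dotted line at the floor. Mean miR-155-5p is 0.0413 in Media, 0.0913 in Media_IL33, 0.0417 in Th2 and 0.151 in Th2_IL33.

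The inflammatory list rose with IL-33 in Th2-grown cells as well (mean 0.74, median 0.50, adjusted p = 9.35e-21, and 0.00356 with an estimated correlation). It held 3 members past the threshold and 4 adjusted over the list alone, and its mean was 0.68 within slide 2 and 0.27 (median 0.20) with normexp background correction. The miR-221 with miR-222 list rose (3 members, mean 0.46, 1 past the threshold, 1 adjusted over the list alone, adjusted p = 0.000394). Its adjusted p was 0.161 with an estimated correlation, and its mean was 0.78 within slide 2 and 0.22 with normexp. The Sfmbt2 family fell by 0.22 on average (median -0.20, 0 past the limma threshold, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, list adjusted p = 0.000315). Its adjusted p was 0.953 with an estimated correlation, and the mean was -0.34 within slide 2 and -0.042 with normexp. The mean was 0.045 with slide as a block, while the test still pointed down (adjusted p = 0.0103), and 0.11 without the 3 arrays that stand apart (0.481).

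With slide as a block all 4 miRNA calls remained. Slide 1 holds no Th2_IL33 array, and within slide 2 (4 arrays with 1) the log2 differences of the 4 were 0.88 to 1.45. A block for replicate number ended the call of miR-222-5p (adjusted p = 0.0578, and 0.0137 to 0.947 over its alternatives), as did leaving out Th2 3 (0.111) or 4 (0.141) or Th2_IL33 1 (0.119), 2 (0.142) or 4 (0.0832). With normexp background correction miR-21a-3p (0.28) and miR-222-5p (0.21) did not pass and miR-155-5p had a log2 difference of 0.41, and miR-146a-5p did not pass in the authors' table (0.93) or with scaling to the percentile over all miRNAs (1.01).

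In the presence of IL-33, growth in Th2 cytokines (Th2_IL33 with Media_IL33) changed 22 miRNAs, 19 higher and 3 lower, each in 4 of 4 experiments. miR-511-3p again had the smallest adjusted p (5.23e-12), with every Media_IL33 array at the floor (at least 4.77-fold higher). This p, too, partly reflects the floor. The same 4 Clcn5 miRNAs rose, miR-362-3p at least 3.76-fold, miR-500-3p 3.53-fold, miR-532-5p 3.49-fold and miR-362-5p at least 2.71-fold. miR-378a-3p rose 2.29-fold from 0.138 to 0.318, miR-342-3p 2.32-fold, miR-99a-5p 2.20-fold, miR-223-3p 2.11-fold and miR-146b-5p 1.93-fold. miR-155-5p, near the floor in Media and Th2, was 1.64-fold higher in Th2_IL33 than in Media_IL33 (0.72 ± 0.19, adjusted p = 0.0246). The 3 that fell form the miR-183 cluster, miR-96-5p (at least 2.18-fold lower, log2 difference -1.31), miR-182-5p (at least 1.79-fold lower, -1.10) and miR-183-5p, for which no fold is given since 1 of 4 Media_IL33 and 0 of 4 Th2_IL33 arrays were well above background.

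The comparisons of Th2 cytokines without and with IL-33 share no array. They do share the variance estimate of each miRNA and the 4 experiments, so their calls are not independent. The overlaps by chance given here assume independent calls. Their log2 differences correlated across the 231 miRNAs with r = 0.641 and rho = 0.760, where miRNAs are not independent replicates. Of the 24 miRNAs past the threshold in either, 18 were higher in both (1.65 by chance) and 2 lower in both (0.026 by chance), while miR-21a-5p and miR-27b-3p passed without IL-33 and miR-155-5p and miR-183-5p with it. With a block for replicate number miR-21a-5p (adjusted p = 0.0233) and miR-27b-3p (0.0238) passed with IL-33 too. Without the 3 arrays that stand apart miR-183-5p passed without IL-33 as well (log2 difference -0.60, limma adjusted p = 0.00984). None of these 4 passed the interaction test of that difference (smallest adjusted p 0.995). The comparisons of IL-33 in medium-grown and Th2-grown cells shared 3 of 5 miRNAs (miR-155-5p, miR-146a-5p and miR-21a-3p, 0.0693 by chance), with r = 0.156 and rho = 0.258 across all miRNAs. With IL-33, miR-378d (1.27), miR-378b (1.15), miR-100-5p (0.89), miR-34a-5p (0.80), let-7c-5p (0.70) and miR-23b-3p (0.61) rose, as did miR-125b-5p and miR-22-3p. miR-21a-5p (0.60 ± 0.23, adjusted p = 0.139) and miR-146a-5p (0.13, 0.588) did not pass.

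Alternative activation rose in the presence of IL-33 too (mean 0.68, median 0.52, 5 past the threshold, 5 adjusted over the list alone, adjusted p = 0.00253). Its adjusted p was 0.616 with an estimated correlation, and its mean was 0.74 with slide as a block, 0.76 within slide 2 and 0.37 with normexp background correction. The miR-17-92 list fell by 0.16 (0 past the limma threshold, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, list adjusted p = 0.0237). With an estimated correlation the adjusted p was 0.616, and the mean within slide 2 was -0.040. With blocks for both slide and replicate number the list did not pass (mean -0.10, adjusted p = 0.0554). The Sfmbt2 family fell by 0.49 (0 past the limma threshold, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, list adjusted p = 6.41e-07). With an estimated correlation the adjusted p was 0.616, and the mean was -0.31 with slide as a block, -0.51 within slide 2, -0.10 with normexp and -0.15 without the 3 arrays that stand apart. By place, a division chosen after the values were seen, the mean was -0.52 for the 20 members in Sfmbt2 and -0.40 for the 7 elsewhere.

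With slide as a block 25 miRNAs passed, with a block for replicate number 24, and with both 37. Within slide 2 (4 arrays with 2) 32 passed, and 16 of 16 named ones kept their direction (log2 -1.14 to 2.81). These 16 were called on the same arrays, most of them on slide 2, so that agreement was nearly built in. miR-155-5p did not pass without Media_IL33 1 (adjusted p = 0.0848) or 2 (0.0791) or Th2_IL33 1 (0.0968), 2 (0.0689) or 4 (0.0549), and its adjusted p over the alternatives run for named miRNAs was 0.00580 to 0.140. miR-183-5p, well above background on 1 Media_IL33 array, did not pass without Media_IL33 2 (0.0542) or 4 (0.0687). With normexp background correction the log2 differences were 0.0034 for miR-183-5p, -0.17 for miR-96-5p and -0.13 for miR-182-5p, none past the threshold. miR-23b-3p did not pass without Media_IL33 1, 2 or 3 or Th2_IL33 1, 2 or 4 (0.0572 to 0.166).

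The interaction tests whether growth in Th2 cytokines altered the response to IL-33, the question of the series. limma called 0 of 231 miRNAs (5 had an unadjusted p under 0.05, smallest adjusted p 0.995). The fitted IL-33 response of miR-155-5p was larger in Th2-grown cells by a log2 difference of 0.69 ± 0.27 (95% confidence interval 0.10 to 1.27), higher in 4 of 4 experiments, which did not pass the correction. Both responses start near the floor and are known as bounds (log2 of at least 0.67 in medium-grown and 1.48 in Th2-grown cells), so the size of their difference is not determined. The fitted difference was 0.23 within slide 2, where Media and Th2 have 1 array each, and 0.29 with normexp background correction. When arrays were weighted by their fit to the model it was the 1 miRNA that passed (1.25 ± 0.23, adjusted p = 0.0158), and it did not pass under the alternatives run for named miRNAs (0.730 to 1). miR-146a-5p, induced by IL-33 in both settings, had an interaction of -0.17 ± 0.22. miR-376c-3p (-3.99 ± 1.70), miR-3063-3p (-3.06), miR-378a-5p (-2.88) and miR-302c-3p (-2.01, lower in 4 of 4) had the most negative values, none past the threshold, and miR-146b-5p (-0.52) and miR-21a-3p (-0.50) did not pass.

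Of the lists, the Sfmbt2 family (mean -0.30) and the Dlk1-Dio3 cluster (4 members including miR-376c-3p, mean -1.08, median -0.17) had a negative interaction with an adjusted p of 0.0472 each, and of 0.869 and 0.502 with an estimated correlation. Each held 0 miRNAs past the limma threshold and 0 adjusted over the list alone, with 0 and 1 at an unadjusted p under 0.05. The adjusted p was 0.0782 each with a block for replicate number and 0.154 each with slide as a block. With both blocks it was 0.000284 and 0.265, and among miRNAs detected on all arrays the Sfmbt2 family passed (0.00653). The means were 0.061 and -0.50 with normexp background correction, and -0.0023 (adjusted p = 0.0594) and 0.033 (0.676) without the 3 arrays that stand apart. Within slide 2, where Media and Th2 have 1 array each, the Sfmbt2 mean was -1.50.

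The remaining lists did not pass the list test in any comparison, or had under 3 tested members, and their values are given for Th2 cytokines without and then with IL-33. Myeloid miRNAs had 3 of 6 past the threshold in both (miR-342-3p, miR-223-3p and miR-146b-5p), with list adjusted p of 0.101 and 0.116. The let-7 list had 1 of 10 (let-7c-5p, 0.611 and 0.508), and miR-23 with miR-27 and miR-24 had 2 of 5 and then 1 (miR-23b-3p in both, 0.0626 and 0.0949). The miR-30 list had 0 of 5 (3 and then 4 at an unadjusted limma p under 0.05), and 3 adjusted over the list alone (miR-30b-5p 0.57 and 0.56, list adjusted p 0.207 and 0.124). With blocks for both slide and replicate number, miR-30b-5p passed without IL-33 (limma adjusted p = 0.0316). With IL-33 miR-30b-5p (0.00832), miR-30c-5p (0.0489) and miR-30d-5p (0.0440) then passed, and no other member did. miR-29 had 0 of 3 (limma, 2 at an unadjusted p under 0.05 in both), with 0 and then 1 (miR-29c-3p) adjusted over the list alone (0.520 and 0.288), and miR-15 with miR-16 had 0 of 4 (0 and then 1 unadjusted, list adjusted p 0.783 and 0.508). Of the stress list miR-34a-5p rose in both, and the hypoxia-induced miR-210-3p did not pass (-0.28 and -0.37). Of 17 miRNAs of other cells or serum on the array 2 were tested, the muscle miRNA miR-206-3p (-0.35 and -0.11) and the brain-enriched miR-128-3p (0.11 and 0.19), and neither passed in any comparison. Over all comparisons 12 of 60 list tests passed, and 2 with an estimated correlation, both for the inflammatory list.

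A set of 5 miRNAs, miR-376c-3p, miR-378a-5p, miR-3063-3p, miR-302c-3p and miR-30b-3p, was low on a few arrays. Their mean log2 signal was -4.46 on Media 1, -4.69 on Media 3, -2.68 on Media 4 and -3.65 on Th2_IL33 2, as against -0.90 on Media 2 and -1.71 to 0.081 on the rest. The Sfmbt2 family also set arrays apart, with a mean of -3.02 on Media 1, -3.39 on Th2_IL33 2 and -0.82 on Media 3, as against -2.29 to -1.78 on the other 13.

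**Figure D3:**
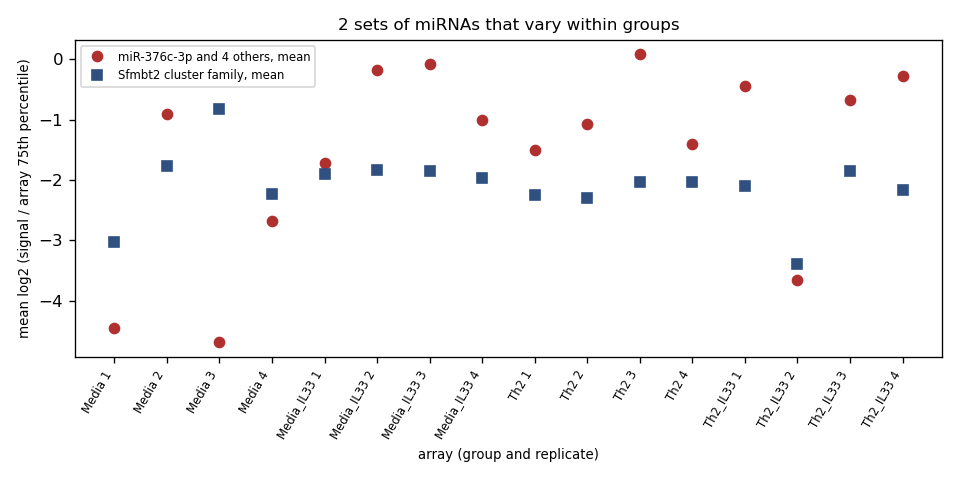
Mean log2 relative signal per array of miR-376c-3p and the 4 other miRNAs that were low with it (red circles) and of the Sfmbt2 family (blue squares), for the 16 arrays by group and replicate. The red circles are at -4.46 on Media 1, -4.69 on Media 3 and -3.65 on Th2_IL33 2.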

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

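The slide and scaling tests of the miRNAs low with miR-376c-3p, and the tests of the Sfmbt2 family without the arrays that stand apart and between the slides of Media_IL33, were chosen only after the result was seen. Single arrays were looked for in 140 groups of 4 values by dividing the gap between an extreme array and its nearest neighbour by the range of the group. In 17 groups this ratio exceeded the 95% critical value of Dixon's test, which flags about 1 in 20 groups of independent normal values, or 7 here. That rate need not hold here. The miRNAs were named from these same data, and many values lie at the floor. Groups with 4 equal values count in the 140 but could not be flagged. The 17 as against 7 therefore do not measure an excess over chance.

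Of these, 6 concern Th2_IL33 replicate 2. On it miR-376c-3p (log2 signal -0.28, ratio 0.843), miR-378a-5p (-4.24, 0.971), miR-3063-3p (-4.82, 0.848), miR-30b-3p (-4.11, 0.867) and miR-669b-5p (-4.67, 0.949) were below the other 3 arrays, and miR-362-3p (-2.13, 0.880) above them. Th2 replicate 4 was above the other Th2 arrays in miR-96-5p (-3.80, ratio 0.998), miR-182-5p (-4.56, ratio 1), miR-183-5p (-4.80, ratio 1) and the number of miRNAs detected (231 as against 223 to 224, ratio 0.875), and below them in miR-342-3p (-1.62, ratio 0.898). The other arrays of the ratios at 1 were all at the floor. In Th2 replicate 3 miR-30b-3p was high (-0.23, ratio 0.858). In Media, replicate 3 was low in miR-378d (-3.93, ratio 0.863) and replicate 4 high in miR-155-5p (-4.10 as against -4.82 to -4.78, ratio 0.938). Media_IL33 replicate 3 was high in miR-146a-5p (-0.81, ratio 0.910), Th2_IL33 replicate 3 low in miR-378a-3p (-2.00, ratio 0.847) and Th2_IL33 replicate 4 high in miR-182-5p (-4.45, ratio 1).

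The first pattern weighed is the low signal of miR-376c-3p, miR-378a-5p, miR-3063-3p, miR-302c-3p and miR-30b-3p on Media 1 and 3, partly on Media 4, and on Th2_IL33 2. A difference between slides is argued against, since the mean of the 5 ranged over 3.79 log2 units among the Media arrays of slide 1 alone, and so is the scaling, since the range among Media arrays was 3.36 without it. For less of the precursor transcripts the other arms of miR-378a and miR-30b were read. They differed by a median of 0.19 between Media 2 and the mean of Media 1 and 3 (miR-378a-3p 0.37, miR-30b-5p 0.01). The 5 miRNAs differed by 2.10 to 6.76. The other arms did not share the drop, but this does not settle the level of the precursors. Probes of miR-378a-3p target nearly the same sequence as those of miR-378b and miR-378d, and Media 2 is a single array. For the other 3 miRNAs no partner arm was tested. RNA handling, labelling or hybridisation of single samples may underlie the pattern and stays open. An effect of the treatments stays open too. Media 1, 3 and 4 were low and Media 2 was not, no Th2 or Media_IL33 array was as low, and in Th2_IL33 only replicate 2 was. In the main limma comparisons none of the 5 miRNAs passed the threshold, and the set as a whole was not tested.

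The second pattern is the lower Sfmbt2 family in Th2_IL33 than in Media_IL33, by -0.49 ± 0.35 (SE of the family mean across arrays, 32 miRNAs), which is within 2 SE of 0. Without the 3 arrays that stand apart, of which Th2_IL33 2 is the only 1 in this comparison, the difference was -0.15 ± 0.10. Th2_IL33 2 had the lowest family mean of the 16 arrays (-3.39), so leaving it out had to bring the difference toward 0. This array may carry most of the difference, but the refit does not tell why it was low. Within slide 2 (4 Th2_IL33 arrays, Th2_IL33 2 among them, with 2) the difference was -0.51 ± 0.35. That is also within 2 SE of 0, so it does not decide on a difference between slides. The Media_IL33 arrays of slide 2 were above those of slide 1 by 0.045 ± 0.070, where -0.97 would be needed. In these arrays, 2 per slide, that argues against a difference between slides as the whole source. The other groups on both slides do not settle it. Media 1, on slide 2, was at -3.02, below the Media arrays of slide 1 (-2.23 to -0.82), and it is 1 of the arrays that stand apart. Th2 4, on slide 2, was at -2.03, with -2.29 to -2.04 on slide 1. With slide as a block the mean difference was -0.31, so a part from slides stays open. Array brightness cannot be told apart: across the 16 arrays with group means removed the family mean and the 75th percentile had r = -0.101 (95% confidence interval -0.618 to 0.477, permutation p = 0.709) and rho = -0.165 (permutation p = 0.541), with r = -0.246 without the 2 farthest arrays. A change with Th2 cytokines, which the design names, stays open and was not tested apart from these.

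Other splits of the 8 arrays of a comparison into 4 and 4 were counted. For Th2 with Media 1 of 35 splits, the real one, called as many miRNAs (22, highest other 2). So it was for Th2_IL33 with Th2 (1 of 35, 4 calls, highest other 0) and Th2_IL33 with Media_IL33 (1 of 35, 22 calls, highest other 0). In these last comparisons the real split also puts 1 side wholly on slide 2. Most of the 35 splits keep same-numbered arrays together, so they do not exclude chance for arrays that the labels pair. For Media_IL33 with Media 2 of 35 splits gave as many, so chance is not excluded there even with the pairing set aside. The real split called 4 and the other, Media 1 and 4 with Media_IL33 3 and 4 against the rest, called 27, several times the real count, which points to a structure of the samples. Among the 8 splits that part every pair of same-numbered arrays, only the real one called as many in each of the 4 comparisons (highest other 2, 0, 0 and 0), while the other 27 splits keep at least 1 pair together. These 8 are too few for a share under 0.05. For the interaction, 100 of 100 drawn splits gave at least the 0 calls of the real one (highest other 16), which decides nothing.

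The numbers of lists past the threshold did not exceed what other splits gave. As many lists passed in 10 of 35 splits for Th2 with Media (3 lists, highest other 8), 35 of 35 for Media_IL33 with Media (1, highest other 5), 15 of 35 for Th2_IL33 with Th2 (3, highest other 4), 16 of 35 for Th2_IL33 with Media_IL33 (3, highest other 7) and 55 of 100 for the interaction (2, highest other 5).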

How the results depend on the processing

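The refit without Media 1, Media 3 and Th2_IL33 2 was chosen only after the results were seen. Of 74 named values, the direction and side of the threshold held for 72 with a block for replicate number, 71 with slide as a block, 71 with both, 70 with quantile normalization, 68 without the 3 arrays, 63 in the authors' table, 63 with the percentile over all miRNAs and 60 with normexp. Leaving out 1 array gave 19 to 30 calls for Th2 with Media, 3 to 5 for Media_IL33 with Media, 3 to 4 for Th2_IL33 with Th2, 19 to 26 for Th2_IL33 with Media_IL33 and 0 for the interaction (limma). The block for replicate number gave 24, 4, 3, 24 and 0. It ended the call of miR-222-5p in Th2_IL33 with Th2, added miR-466f-5p and miR-466j in Th2 with Media and miR-21a-5p (adjusted p = 0.0233) and miR-27b-3p in Th2_IL33 with Media_IL33, and changed no other call. Higher and lower calls in Th2 with Media were 20 and 2, but 18 and 11 with quantile normalization, 15 and 9 in the authors' table, 31 and 33 with array weights, and 17 and 13 without Media 3. Media_IL33 with Media called 1 miRNA with normexp, 1 among miRNAs detected on all 16 arrays (178 tested), and 2 with the floor multiplied by 2, 2 within slide 1 and 2 without the 3 arrays. Th2_IL33 with Th2 called 2 with the percentile over all miRNAs, normexp, the authors' table and miRNAs detected on all arrays. Th2_IL33 with Media_IL33 called 12 with the percentile over all miRNAs, 14 without normalization, in the authors' table, among miRNAs detected on all arrays and without a filter (1247 tested), 37 with both blocks and 71 with array weights, which also gave 64 for Th2 with Media and 1 for the interaction. For the filters the number tested accounts in part for the counts. The constant that normexp adds to every spot draws log2 differences of dim miRNAs toward 0. For the other alternatives the cause was not tested. Values that changed sign without passing the threshold were those of miR-155-5p in Th2 with Media (-0.063 with the percentile over all miRNAs, -0.093 in the authors' table, -0.16 without the 3 arrays) and miR-378a-3p in Th2_IL33 with Th2 (0.053 and 0.0030 with the same scalings, 0.095 with slide as a block and 0.20 with both blocks). Others were, in the interaction, miR-146b-5p (0.065), miR-21a-3p (0.045) and miR-223-3p (0.0021) with normexp, miR-223-3p with both blocks (0.033), and miR-5615-5p (0.066) and miR-21a-5p (0.027) without the 3 arrays. miR-183-5p, past the threshold in Th2_IL33 with Media_IL33, was at 0.0034 with normexp, and the Sfmbt2 family in Th2_IL33 with Th2 at 0.11 without the 3 arrays. Of 12 list calls 2 held with an estimated correlation. The median log2 difference over all tested miRNAs was 0.103 and 0.105 in the IL-33 comparisons with the percentile over all miRNAs, and -0.164 to 0.200 over the comparisons without normalization. Signal over background limits miR-155-5p, miR-96-5p, miR-182-5p and miR-183-5p, and the constant that normexp adds compresses these and other dim miRNAs. A scan batch block coincides with slide and was not run.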

Other observations

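The test of neighbouring miRNA genes outside the Sfmbt2 cluster was chosen only after the result was seen, and the miRNAs named in the first paragraph beyond the fixed rule were chosen after their values were seen. In the reference gene table (GRCm38.p6) several of the miRNAs that responded to Th2 cytokines share a host gene. miR-362, miR-500 and miR-532 lie in Clcn5 with miR-188 and miR-501. Of this group miR-532-3p (log2 difference 0.48, adjusted p = 0.114, without IL-33, and 0.53, adjusted p = 0.0804, with it) and miR-188-5p (-0.19 and -0.12, adjusted p = 0.425 and 0.551) did not pass, so 4 of the 6 tested miRNAs of the group passed. With IL-33, miR-532-3p passed with slide as a block (0.63, limma adjusted p = 0.0498) and with both blocks (0.66, 0.0351). miR-182, miR-183 and miR-96 share the transcript Mirc35hg, and miR-183-5p was at -0.41 without IL-33 (adjusted p = 0.0964). miR-23b and miR-27b lie in Aopep beside a copy of miR-24, whose product miR-24-3p was at 0.43 and 0.41 (adjusted p = 0.187 and 0.250). miR-100 lies in Mir100hg beside a let-7a gene (Mirlet7a-2). Single miRNAs in host genes included miR-511 (Mrc1), miR-378a (Ppargc1b), miR-378b (Msi2), miR-342 (Evl), miR-22 (Mir22hg), miR-223 (F630028O10Rik) and miR-146b (Gm36493), and of those that responded to IL-33 miR-21a (Vmp1) and miR-155 (Mir155hg).

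Neighbouring miRNA genes may share a transcript and so change together with Th2 cytokines. Outside the Clcn5 group, 120 pairs of tested miRNAs (54 miRNAs) come from genes within 20000 bases of each other. The median absolute difference between the log2 changes of a pair in Th2 with Media was 0.223, as against a median of 0.327 when log2 changes were shuffled among miRNAs (1-sided permutation p = 0.0406). Of these pairs 90 are among 20 miRNAs of Sfmbt2. Over the other 30 pairs (34 miRNAs) the medians were 0.253 and 0.326 (1-sided permutation p = 0.180), so the test does not show a smaller difference outside that cluster, and a shared transcript stays open. Pairs that share a miRNA are not independent, and array probes of related sequences can share signal, which this test does not separate from a shared transcript.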
